A study of Homo sapiens with 6 samples.

How the data were processed

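Total RNA of T47D cells was measured by RNA-seq in 6 libraries, 3 with a control siRNA (siNC) and 3 with an siRNA against ELF5 (siELF5), each taken 48 h after transfection. Libraries were made with the TruSeq RNA kit v2, per the labels, a kit that does not mark strand. Groups and replicate numbers came from the sample titles. Nothing in the labels says whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

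The build hg19 and the tools STAR 2.6 (an aligner), Subread, featureCounts 1.6.3 (a read counter) and DESeq2 1.22.1 were used, per the submitters' processing notes, whose order and settings are not given in the sources used here. Counting options, including strand and shared reads, are likewise not given. A table of the whole series was used. Its deposited per-library values and their mean are signal values, which the spacing of the values shows to be gene counts divided by a size factor per library, and are called normalised read counts here. The deposited log2 fold change and its standard error, the deposited test score (the fold change divided by its standard error) and the deposited p-value and adjusted p-value are the authors' own DESeq2 results, per the file headers. These served only for comparison and entered no test.

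Every non-zero value in a column was a whole multiple of that column's smallest value (100% of values, within a tolerance of 1e-06), so whole reads were recovered. The recovered totals were 66.8 M to 83.7 M reads per library, and 18767 to 19194 genes had a read. The 10 most abundant genes took 4.03% to 4.51% of reads. At this depth counting error is small for all but low genes. Pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.54 to 12.9, so none was taken for a copy of another.

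The main test was limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, on log2(value + 1), over genes with a mean of at least 10, without covariates. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Of 26364 genes in the table, 21390 had a read and 16032 were tested. On the recovered reads edgeR 4.0.16 (quasi-likelihood) called 7583 genes and DESeq2 1.42.0 called 7128.

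A total of 29 gene lists was fixed before the data were examined, and the 28 with at least 5 measured members were tested with camera at a preset correlation of 0.01, with adjustment over lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its degrees of freedom from the 6 libraries and not from the genes, so few lists could pass. A list that fails it is not thereby shown to owe its call to correlated members. Members were also counted after adjustment over the list alone, and these counts are given where they differ from those over all genes. The rule for named genes and the alternatives not marked below as added were fixed at the same time. Lists could share members, so calls for different lists are not independent.

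Named genes were ELF5 and EHF; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 50, groups that did not overlap and a gene symbol (no LOC, LINC, antisense or clone names); and, from each list, up to 3 members past the threshold with the smallest adjusted p, or up to 4 from the junction, epithelial regulator and mesenchymal lists. If no member passed, the one with the smallest p could be named. Genes with near-identical copies were to be named as uncertain. Other genes are marked as chosen after their values were seen, and some genes that the rule takes are not reported here.

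GC content and length came from the longest GENCODE 29 transcript of each symbol, older symbols included, found for 14941 of the tested genes (93.2%). The GC correction subtracts, per library, a loess curve (span 0.3) of each gene's deviation from its mean on GC content. The library GC score is the median deviation of the 10% of genes with the highest GC minus that of the fifth of the 10 classes. The siRNA groups do not overlap in this score, so as a covariate it also takes up part of the difference between groups and widens the standard errors. The 3' UTRs of 12992 tested genes (81%) were searched for 7-base motifs. The reference is GRCh38 and the counts are on hg19, so no coordinates are printed and the reference serves only for names, sequence and neighbours.

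The motif search took 11133 genes with a mean of at least 100 and related the GC-corrected log2 fold change, limited to 1.5 either way, to the number of sites of each of 16384 motifs, with 3' UTR length and dinucleotide content in the model. It was compared with 100 permutations of the genes' values after removal of these terms and repeated by finding the motif in 5566 randomly drawn genes and testing it in the other 5567. A further model held the sites of CACTAAC in the 3' UTR and in the coding sequence together, with length and dinucleotide content of both. The search was added after seeing the data. Intervals of list medians are 95% bootstrap intervals from 1000 draws of the members.

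The tests were tried on simulated data. For siELF5 against siNC with 16032 genes, limma recovered 45 of 67 genes changed by 1.25-fold, 53 of 67 changed by 1.5-fold and 53 of 66 changed by 2-fold, with 9 false calls among 160. Camera called the 1 shifted list and none of 27 others. Each gene was drawn independently there, so false calls for lists whose members move together were not tried. In the motif search a planted motif ranked first for 3 of 3 motifs at -0.13 per site and for 2 of 3 at -0.05, over 11133 genes.

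Alternatives covered the pseudocount, the filter, TMM, total-count and quantile scaling, the trend, a replicate block, edgeR and DESeq2, stricter thresholds, leaving out each library, the estimated correlation, and, added after seeing the data, GC and length corrections and leaving out seed-site genes. Searches and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.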

Results

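T47D cells, an established human luminal A breast cancer line, received either a control siRNA (siNC) or an siRNA against ELF5 (siELF5), and RNA was taken 48 h after transfection. Each group held 3 libraries, and each group received 1 siRNA. The labels give the control and the ELF5 siRNA different catalogue numbers, and whether they differ in chemistry as well as in sequence is not given in the sources used here, so every fold change compares both products and targets. The total of assigned reads was 66.8 M, 83.3 M and 75.6 M in siNC replicates 1, 2 and 3, and 83.7 M, 76.4 M and 72.4 M in siELF5 replicates 1, 2 and 3. The series title sets the part of ELF5 in epithelial integrity apart from that of EHF, so the comparison asks which genes, and in particular which epithelial genes and whether EHF, differed after ELF5 knockdown.

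ELF5, an ETS-family transcription factor of the mammary luminal lineage, fell in every siELF5 library to between 27.8% and 28.4% of the siNC mean. Its normalised read count was 13094.5 ± 164 (SD, n = 3) in siNC and 3680 ± 43.7 (SD, n = 3) in siELF5, a log2 fold change of -1.83 (SE 0.033, limma adjusted p = 3.26e-12). The level of the target thus matched the label of all 6 libraries.

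EHF, the ETS factor gene that follows ELF5 on chromosome 11 in GRCh38.p14, fell much less. Its normalised read count was 51519 ± 1253 (SD, n = 3) in siNC and 42476 ± 821 (SD, n = 3) in siELF5, 82.4% of the siNC mean, with a log2 fold change of -0.28 (SE 0.029, limma adjusted p = 8.23e-06). The call for EHF did not hold with the library GC score as a covariate, where the log2 fold change was -0.20 (adjusted p = 0.122) and its standard error rose from 0.029 to 0.076. Of 21 measured ETS family genes, 9 rose, 9 fell and 3 did not pass the test. ELF3, an epithelial ETS factor, fell by 1.13 on the log2 scale (SE 0.049), and ETV4 rose by 1.10 (SE 0.106). As a set the family did not stand apart from other genes (camera adjusted p = 0.612).

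**Figure D1:**
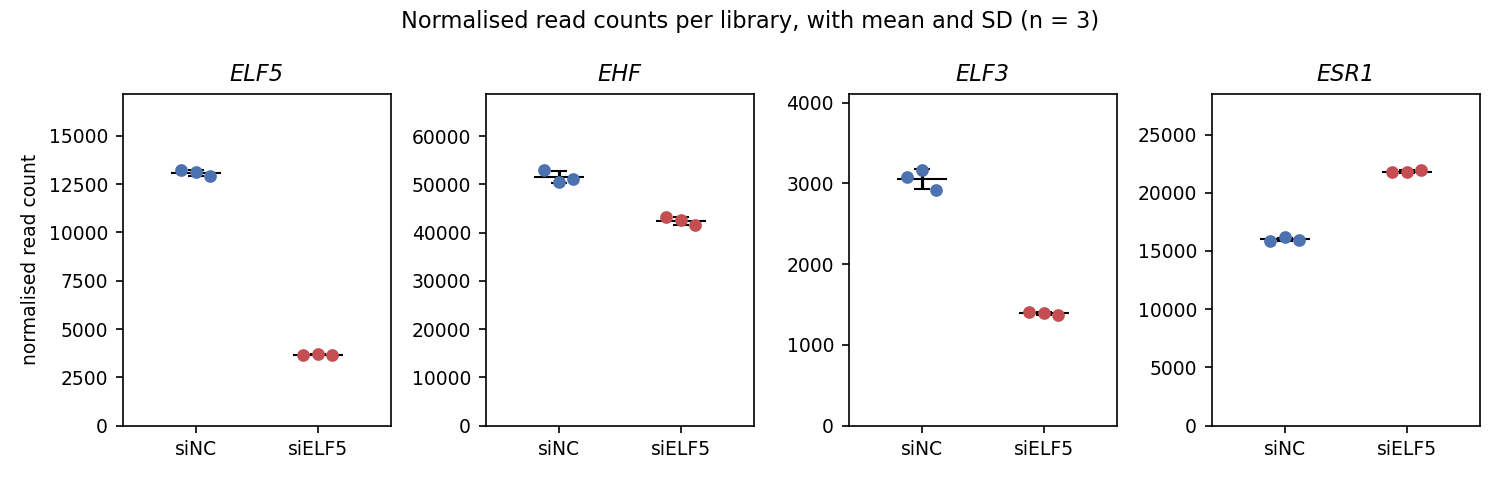
Normalised read count (vertical axis, from 0) of ELF5, EHF, ELF3 and ESR1 in each siNC (blue) and siELF5 (red) library, with the mean and SD of 3 libraries in black. The siELF5 libraries lie below all siNC libraries for ELF5, EHF and ELF3 and above them for ESR1.

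Many genes differed, most of them by little. Of 16032 genes tested, 7559 changed (limma adjusted p under 0.05), 3818 of them higher and 3741 lower in siELF5. Of the changed genes, 5878 (77.8%) differed by less than 1.5-fold, and 664 differed by at least 2-fold, 492 upward and 172 downward. The authors' deposited table called 7103 genes, 3562 higher and 3541 lower. The 3 siELF5 values lay on one side of the 3 siNC values for 8958 of the tested genes (55.9%), against 10% by chance.

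The direction of change followed base composition at its upper end. Among the 1494 genes with the highest transcript GC content (61.7% to 76.8%), 930 rose and 52 fell, with a median log2 fold change of 0.43. The same genes also differed among the siNC libraries, with median deviations of -0.36, -0.19 and -0.06 in replicates 1, 2 and 3. After a per-library GC correction 386 of these genes rose and 383 fell, and 7386 genes were called in all. The correction centres genes of like GC content in every library, so this balance follows from it. It would remove an effect of the siRNA on GC-rich genes as well as a bias of the libraries. With the library GC score as a covariate, 1138 genes were called, 501 higher and 637 lower, and the median standard error over the tested genes rose from 0.063 to 0.151. Both settings were added after the GC trend was seen.

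**Figure D2:**
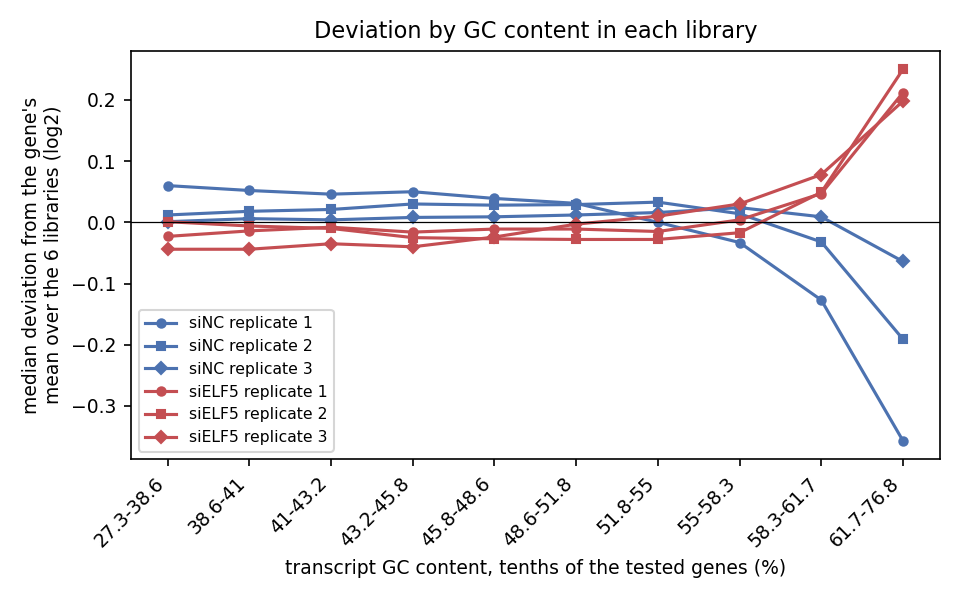
Median deviation of genes from their mean over the 6 libraries (vertical axis, log2) against transcript GC content in 10 classes of equal size (horizontal axis, %), with a line for each siNC (blue) and siELF5 (red) library. In the class of highest GC the siELF5 libraries lie between 0.20 and 0.25 and the siNC libraries between -0.36 and -0.06.

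A 7-base motif, found by a search over all 7-base motifs in these data, also went with the direction of change. Of 3330 genes that fell and whose 3' UTR could be searched, 539 (16.2%) carried CACTAAC or ACTAACA in the 3' UTR, against 10.1% of all genes searched. Either motif is called a seed site in what follows, as a name only, since the siRNA sequences are not given in the sources used here.

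The genes that fell most were largely of low or middle GC content. TGFB2, a TGF-beta ligand, fell from 307 ± 35.9 to 51.8 ± 11.8 (SD, n = 3), a log2 fold change of -2.56 (SE 0.187, limma adjusted p = 3.5e-07). TRPM8, a cold-sensing cation channel, had a log2 fold change of -3.37, and KRT4, a keratin of stratified epithelia, of -2.99. SYNPO2 (-2.38), UGT2B15 (-2.27), DISC1FP1 (-2.21), NBPF13P (-3.35), ZNF812 (-2.58) and CYP4Z2P (-2.49) were also among the 10 largest decreases. NBPF13P, ZNF812, CYP4Z2P and UGT2B15 belong to families of close copies, so their reads could be split with relatives. With the library GC score as a covariate 8 of the 10 still passed the threshold, all but SYNPO2 and UGT2B15. Their log2 fold changes were then -2.03 and -1.87, and their standard errors had risen from 0.393 to 0.981 and from 0.222 to 0.616.

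The 10 largest increases were mostly in GC-rich genes. They were OVCA2 (log2 fold change 4.56), NPW (4.09), TPGS1 (3.92), LRRC26 (3.74), C4orf48 (3.45), PDF (3.36), MIR6087 (3.08), CCDC85B (2.96), WISP2 (2.87) and MTHFS (2.83). The GC-corrected value of MIR6087 was 1.86. Transcript GC content was above 60% in 8 of them, and with the library GC score as a covariate 1 of the 10, WISP2, passed the threshold. NPW was then at 2.89, with a standard error up from 0.589 to 1.39, and the other 8 lay between -0.99 and 1.16. In GENCODE 29 the exons of OVCA2 lie wholly (100%) in exons of DPH1, and 48.3% of PDF, 34% of MTHFS and 27.5% of LRRC26 is shared with same-strand neighbours, so these 4 values are uncertain. WISP2, a secreted CCN-family protein induced by estrogen, rose from 35.1 ± 8.02 to 259.3 ± 29 (SD, n = 3), with a standard error of 0.199 and a limma adjusted p of 2.12e-07. Among increases chosen after the values were seen, for passing the test with both GC adjustments, were ID1, a BMP-induced inhibitor of differentiation (log2 fold change 2.08), and PGLYRP2, an amidase that cleaves peptidoglycan (2.04).

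Genes of cell junctions moved in both directions. Of 18 adherens junction genes, 7 rose and 8 fell. CTNNB1, the gene of beta-catenin, rose by 0.42 (SE 0.027) and carries a seed site, and CDH3, P-cadherin, rose by 0.50 (SE 0.038). LIMA1, an actin-binding protein, fell by 0.57 on the log2 scale (SE 0.035), and CTNNA1, alpha-catenin and a seed-site gene, fell by 0.30 (SE 0.03). For CDH1, E-cadherin, which was picked after its values were seen, the log2 fold change was 0.05 (adjusted p = 0.133), and it passed after the GC correction with 0.08 (adjusted p = 0.00472). Of 27 tight junction and polarity genes, 11 rose and 5 fell. CLDN1 rose by 0.39 (SE 0.034) and PARD6B fell by 0.24 on the log2 scale. CLDN3 rose by 1.76 and LSR by 0.80, but both are GC-rich (69.2% and 64.8%), and their GC-corrected log2 fold changes were 1.00 and 0.36. Of 18 desmosome and hemidesmosome genes, 8 rose and 5 fell. DST and PKP4 fell by 0.56 and 0.33, while LAMB3, a chain of an epithelial basement membrane laminin, rose by 0.94. After the GC correction 5 genes of this list rose and 10 fell, its median went from 0.07 to -0.12 and its camera direction turned downward (adjusted p = 0.321).

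None of these 3 junction lists passed the set test (camera adjusted p = 0.879 for adherens junction, 0.42 for tight junction and polarity, 0.612 for desmosome and hemidesmosome). For tight junction and polarity the median log2 fold change (-0.02) and the mean (0.17) differed in sign. Adjusted over the list alone, 6 tight junction genes fell in place of 5, and the other counts were the same.

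Epithelial transcription and splicing regulators fell more often than they rose. Of 24 genes, 6 rose, 11 fell and 7 did not pass. GRHL3, a grainyhead factor of epithelial barrier formation, fell by 1.63 on the log2 scale (SE 0.11), and TFAP2C, a luminal AP-2 factor, by 0.36 (SE 0.039). The list did not pass the set test (camera adjusted p = 0.115) and passed it after the GC correction (adjusted p = 0.0235, or adjusted p = 0.452 with an estimated correlation), as under 4 of 21 alternatives, all with a GC adjustment (adjusted p over the 21 from 0.00357 to 0.464). Of 20 mesenchymal genes, 7 rose and 3 fell, and adjusted over the list alone 9 rose (camera adjusted p = 0.332). ACTA2, smooth muscle actin, rose by 1.05 and S100A4 by 0.68, whereas TGFB2 fell, and TGFB1 rose by 1.78 from a low level, with a GC content of 63.5%.

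Estrogen response and luminal genes rose. Of 30 estrogen response genes, 22 rose and 3 fell, with a median log2 fold change of 0.32, and adjusted over the list alone 23 rose and 4 fell. SERPINA1, alpha-1-antitrypsin, rose from 6728 ± 11.2 to 14982 ± 59.1 (SD, n = 3), a log2 fold change of 1.15 (SE 0.03, limma adjusted p = 5.01e-11). CA12, a carbonic anhydrase, rose by 0.61 (SE 0.028) and IGFBP4 by 0.60 (SE 0.031), with a GC content of 62.5% and a GC-corrected value of 0.32 for IGFBP4. The estrogen response list passed the set test (camera adjusted p = 1.25e-07), but not when the correlation between genes was estimated (adjusted p = 0.406). The estimate was 0.054, and that version also rests on the few degrees of freedom of 6 libraries. After the GC correction its median was 0.29 and 22 members rose, and with the library GC score as a covariate its median was 0.26, 11 rose and 2 fell.

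Of 24 luminal identity genes, 16 rose and 5 fell (camera adjusted p = 0.00399, or adjusted p = 0.464 with an estimated correlation). CA12 is a member of this list as well as of the estrogen response list. ESR1, the estrogen receptor alpha gene, rose from 15985 ± 157 to 21822 ± 102 (SD, n = 3), a log2 fold change of 0.45 (SE 0.028), and carries a seed site. AGR2, a secretory-pathway disulfide isomerase, rose by 0.56 (SE 0.029). The call for this list was lost with the library GC score as a covariate, where its median went from 0.27 to 0.19, and without the seed-site genes. Of its 4 seed-site members 0 fell, so leaving them out took away no fallen gene. Of 21 progesterone response genes, a list that includes ELF5 itself, 6 rose and 7 fell (camera adjusted p = 0.817), and adjusted over the list alone 7 rose and 8 fell. Among them CCND1 rose by 0.59 and BCL6 fell by 0.42.

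Interferon response genes rose as well. Of 30 measured, 17 rose and none fell, with a median log2 fold change of 0.33 (camera adjusted p = 0.000572, or adjusted p = 0.464 with an estimated correlation). IFI6 rose by 1.20 (SE 0.126), PSMB8, an immunoproteasome subunit, by 0.52 (SE 0.06) and BST2, tetherin, by 0.32 (SE 0.032). After the GC correction the median of the list was 0.32, and with the library GC score as a covariate it was 0.31, with 4 members risen.

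Of 3 further lists that passed upward, each had an adjusted p of 0.0452 by camera. Among p53 targets 12 of 23 rose and 4 fell, with CCNG1 (0.65) and FDXR (0.93, GC content 61.8%, 0.51 with the library GC score as a covariate) among the increases, and the adjusted p was 0.464 with an estimated correlation. Among immediate early and MAPK feedback genes 14 of 25 rose and 6 fell, with DUSP4 (0.55) and SPRED1 (0.64) among the increases (adjusted p = 0.504 with an estimated correlation). This list passed under 10 of 21 alternatives, and was lost without siNC replicate 2 (adjusted p = 0.0544), siELF5 replicate 1 (adjusted p = 0.0546) or siELF5 replicate 2 (adjusted p = 0.0566) and with the GC score (adjusted p = 0.15). The p53 list passed under 16 of 21, and was lost without siELF5 replicate 2 (adjusted p = 0.0614). Among Notch and Wnt genes 13 of 27 rose and 5 fell, and DLL1, a Notch ligand, rose by 1.52 (SE 0.093), or 0.96 with the library GC score as a covariate. NOTCH1 and JAG2 rose by 0.87 and 1.03, and are GC-rich (62.9% and 64%), with GC-corrected values of 0.56 and 0.64. The Notch and Wnt list had an adjusted p of 0.464 with an estimated correlation and did not pass after the GC correction (adjusted p = 0.152), where its median went from 0.28 to 0.16. It passed under 10 of 21 alternatives, and was lost without siELF5 replicate 2 (adjusted p = 0.0716).

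Ribosomal protein genes fell together. Of 33, 27 fell and 3 rose, with a median log2 fold change of -0.20 (camera adjusted p = 1.25e-07, or adjusted p = 0.464 with an estimated correlation), and the median was -0.17 after the GC correction and also with the library GC score as a covariate, where 10 fell and none rose. RPLP0 fell by 0.42 (SE 0.027), RPS23 by 0.35 (SE 0.03) and RPS9 by 0.34 (SE 0.029) on the log2 scale; all 3 have processed pseudogenes that could share reads. Of 28 genes of the G1/S transition and replication, 16 fell and 4 rose (camera adjusted p = 0.046, or adjusted p = 0.504 with an estimated correlation), and adjusted over the list alone 5 rose. CDC45, a helicase subunit, fell by 0.44, as did POLA1, a DNA polymerase subunit gene with a seed site. This list did not pass after the GC correction (adjusted p = 0.103), where its median went from -0.09 to -0.06, and passed under only 6 of 21 alternatives. It was lost on leaving out any single library other than siELF5 replicate 1 (adjusted p = 0.0544 to 0.082), and with equal column totals, quantile scaling, no trend, a mean of at least 50, the GC score or seed-site genes left out. Of 30 G2/M and mitosis genes, 12 fell and 4 rose (camera adjusted p = 0.115), and of 21 alternatives (adjusted p from 0.0423 to 0.968) this list passed only without siELF5 replicate 1 (adjusted p = 0.0423). FOXM1, a mitotic transcription factor and a seed-site gene, fell by 0.32.

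In all 8 of the 28 lists tested passed, 6 upward and 2 downward. None passed with an estimated correlation, where camera gave 1 list with an unadjusted p under 0.05 and fry, which asks only whether a list's genes move on balance one way, called 23. With so few libraries the estimated version could hardly pass any list, so it neither upholds nor overturns the 8 calls. Without siELF5 replicate 2 the number of lists past the threshold with the preset correlation was 4. Estrogen response, interferon response, luminal identity and ribosomal proteins were those that passed.

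**Figure D3:**
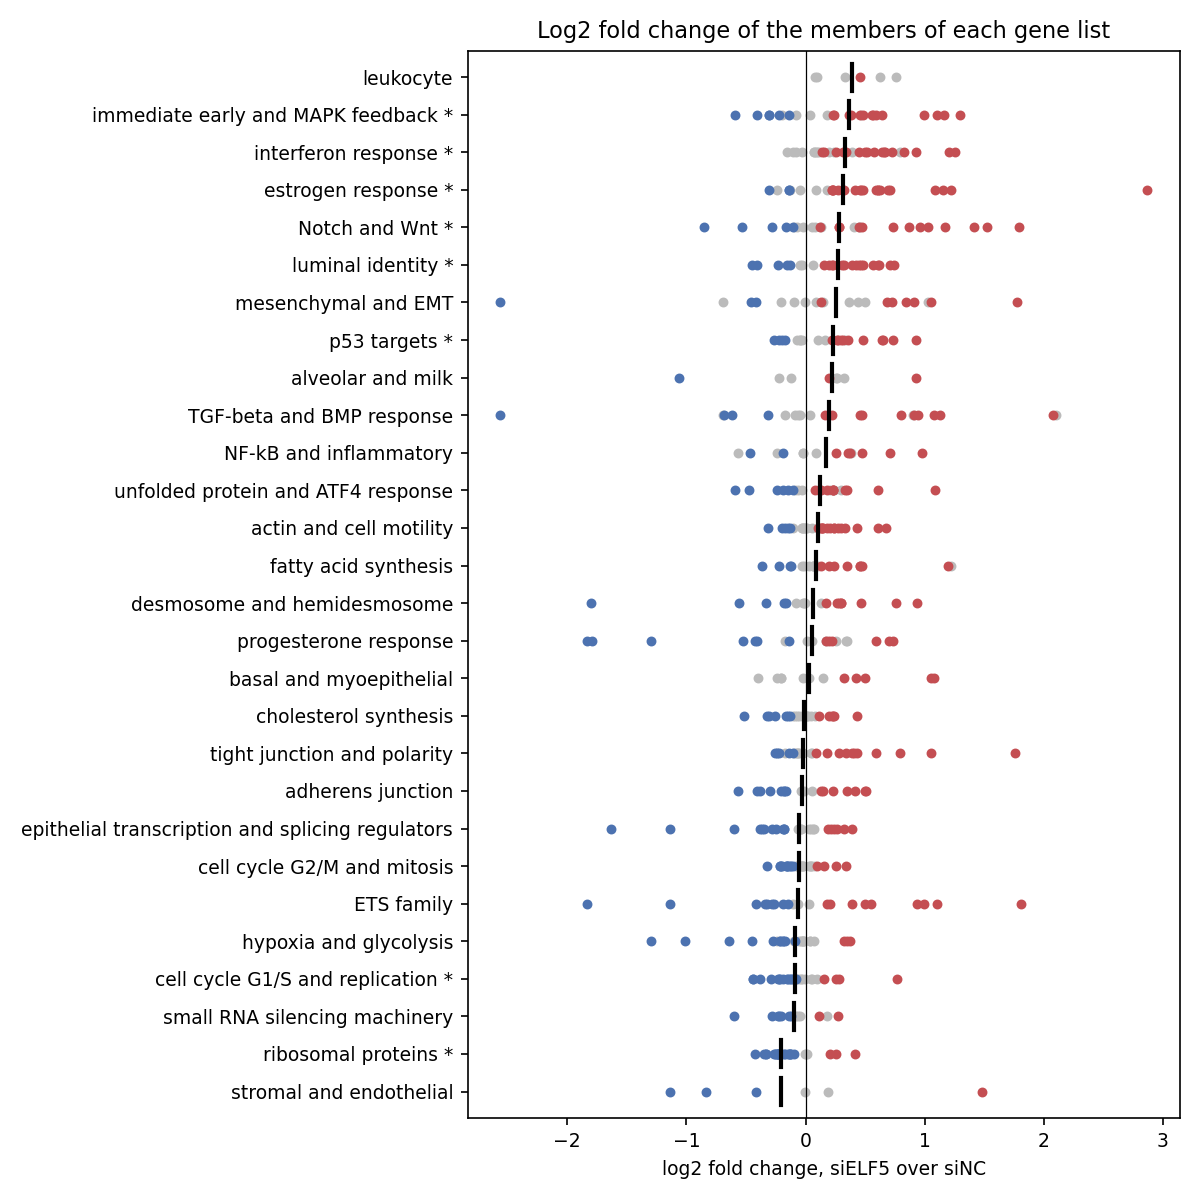
Log2 fold change, siELF5 over siNC (horizontal axis), of each measured member of 28 gene lists, with risen members in red, fallen members in blue and members that did not pass in grey. Black bars mark list medians and asterisks the 8 lists past the threshold by camera with the preset correlation; estrogen response has a median of 0.32 and ribosomal proteins of -0.20.

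The lists not yet described did not pass the set test as planned, and 2 of them passed under some alternative. DICER1, the endonuclease that makes microRNAs, fell by 0.60 (SE 0.04) among 15 small RNA silencing genes, of which 2 rose and 7 fell (camera adjusted p = 0.0532). This list passed downward under 3 of 21 alternatives (adjusted p from 0.0211 to 0.464), which were no filter on low values (adjusted p = 0.0211), leaving out siNC replicate 1 (adjusted p = 0.0436) and leaving out siELF5 replicate 3 (adjusted p = 0.0302). Of 25 hypoxia and glycolysis genes, 3 rose and 11 fell (adjusted p = 0.13), while with the library GC score as a covariate 3 rose and 1 fell and the camera direction was upward (adjusted p = 0.892). ADM, adrenomedullin, fell by 1.01. Of 30 actin and cell motility genes, 16 rose and 5 fell (adjusted p = 0.0975), and the list passed upward with quantile scaling alone (adjusted p = 0.00618, where the 21 alternatives ran from 0.00618 to 0.464). TPM1, a tropomyosin, fell by 0.31 on the log2 scale. Of 24 unfolded protein and ATF4 response genes, 11 rose and 6 fell (adjusted p = 0.132), and adjusted over the list alone 13 rose; CREB3L2, a seed-site gene, rose by 0.61. Of 22 TGF-beta and BMP response genes, 10 rose and 4 fell (adjusted p = 0.264), and adjusted over the list alone 11 rose. SKIL, a SMAD corepressor, fell by 0.62. Of 20 fatty acid synthesis genes, 8 rose and 4 fell (adjusted p = 0.198). FASN, fatty acid synthase, rose by 0.48, but its GC content was 65.3% and its GC-corrected log2 fold change was -0.001, and with the library GC score as a covariate it was -0.289. Of 24 cholesterol synthesis genes, 6 rose and 7 fell (adjusted p = 0.612), and SC5D fell by 0.52. Of 14 NF-kB and inflammatory genes, 6 rose and 2 fell (adjusted p = 0.388), and adjusted over the list alone 3 fell. NFKB2 (0.26) had a GC-corrected value of -0.02.

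Of 13 basal and myoepithelial genes, 5 rose and none fell (camera adjusted p = 0.13), and adjusted over the list alone 4 rose, with EGFR, the epidermal growth factor receptor, higher by 1.08 (SE 0.071). Of 8 alveolar and milk genes, 2 rose and 1 fell (adjusted p = 0.612). FOLR1, a folate receptor, rose by 0.93, and ALDH1A3, a retinaldehyde dehydrogenase gene with a seed site, fell by 1.06. Of 6 leukocyte genes 1 rose, and none did when adjusted over the list alone (camera adjusted p = 0.332). Of 6 stromal and endothelial genes, 1 rose and 3 fell (adjusted p = 0.696); CSPG4 rose by 1.48, and COL1A1 fell by 0.42, with log2 fold changes of -0.61 after the GC correction and -0.92 with the library GC score as a covariate. No mitochondrially encoded gene was tested, because the table listed 0 of them.

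Among the other named genes, 11 calls were lost with the library GC score as a covariate, not all for the same reason. PARD6B (log2 fold change -0.23), BST2 (0.28), CTNNA1 (-0.21) and TPM1 (-0.20) had at least 0.6 of their log2 fold change, and their standard errors rose from between 0.03 and 0.037 to between 0.076 and 0.09. CLDN3 (0.25), LSR (0.15), NOTCH1 (0.29) and JAG2 (0.28) lost most of theirs, and their standard errors rose by factors of 1.03 to 1.47. For IFI6 (0.66), TGFB1 (0.72) and NFKB2 (0.15) the fold fell and the standard error rose by factors of 2.19 to 2.57. The library kit does not mark strand, and opposite-strand genes overlap 30.1% of the exons of ACTA2, 27.5% of ALDH1A3, 21.4% of TPM1, 20.6% of PSMB8 and 15.9% of FOXM1. A same-strand transcript overlaps 26.6% of TGFB2. The values of these 6 genes are uncertain for that reason.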

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

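The alternatives on GC content, length and seed sites were chosen after seeing the data; the others were planned. ELF5 kept its direction and call under every alternative, with a log2 fold change between -1.84 and -1.79. EHF stayed between -0.291 and -0.204 and lost its call only with the library GC score (-0.204, adjusted p = 0.122). The number of genes changed stayed within 1.5 times of 7559 except for 664 with at least a 2-fold change, 482 with the GC correction and at least a 2-fold change, and 1138 (501 higher, 637 lower) with the GC score. Of those 1138, 1040 were shared with the main result in direction and 12 were opposite; of 7386 with the GC correction, 6120 were shared and 97 opposite. Leaving out 1 library gave 6164 to 7312 genes. The number of lists past the threshold moved from 8 to 4 with a mean of at least 50, equal column totals, no trend, or seed-site genes left out, to 5 with the GC score and to 0 with an estimated correlation, where camera gave 1 at an unadjusted p under 0.05 and fry called 23. Leaving out 1 library gave 4 to 8 lists, with 4 without siELF5 replicate 2. Estrogen response, interferon response and ribosomal proteins passed under 20 of 21 alternatives, all but the estimated correlation. The lists that passed differed between alternatives. Beyond the 8, small RNA silencing passed with no filter and without siNC replicate 1 or siELF5 replicate 3, G2/M and mitosis without siELF5 replicate 1, actin and cell motility with quantile scaling, and epithelial regulators under 4 GC settings. Some lists that passed under none of the alternatives turned direction: desmosome and hemidesmosome with the GC settings, hypoxia and glycolysis and tight junction and polarity with the GC score, cholesterol synthesis with the GC score and quantile scaling, adherens junction with quantile scaling and without seed-site genes, and progesterone response with a mean of at least 50. Of 105 named genes besides ELF5 and EHF, 62 kept their call with the GC score, 39 lost it and 4 reversed: OVCA2 (-0.99), LRRC26 (-0.618), C4orf48 (-0.289) and FASN (-0.289, adjusted p = 0.0366). Of the 43 calls that ended with the GC score, EHF and 3 reversed genes included, 19 had at least 0.6 of their log2 fold change, and the median standard error of all tested genes rose from 0.063 to 0.151. NFKB2 was at -0.017 and FASN at -0.001 with the GC correction, with or without the block, and NFKB2 at -0.013 with GC and length corrected. For the reversals with the GC score and the moves with GC correction, scaling, trend and seed-site settings the cause was not tested. Depth limits genes near the minimum mean of 10.

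With the replicate block 7174 genes changed, 7078 of them shared, 7 lists passed, with immediate early and MAPK feedback lost (adjusted p = 0.0521), and 7144 genes changed with the block and the GC correction. Same-numbered libraries did not deviate together (correlations across genes of -0.02, -0.063 and -0.155), and not every library correlated best with its own number: siELF5 replicate 2 did so with siNC replicate 3 (0.164). No pairing by number was thus seen, though a weak effect shared by same-numbered libraries could be missed by this check.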

Other observations

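The tests of the GC trend, the motif in held-out genes and the other orders of its bases, the tests of the estrogen list and the reverse complement were chosen after the result was seen, as were the genes named next.

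Among the 10 higher and 10 lower genes with the smallest adjusted p were the following. SERPINA6, corticosteroid-binding globulin, rose from 27950 ± 505 to 60603 ± 1100 (SD, n = 3), a log2 fold change of 1.12 (SE 0.028, limma adjusted p = 5.01e-11). MGP, matrix Gla protein, rose by 1.12 (SE 0.036) and LAMC1, the laminin gamma-1 chain, by 1.05 (SE 0.031), and LAMC1 has a seed site. IGFBP5, an insulin-like growth factor binding protein, fell from 169080 ± 2979 to 63627 ± 1656 (SD, n = 3), a log2 fold change of -1.41 (SE 0.029, limma adjusted p = 9.04e-12). CLU, clusterin, fell by 0.88 (SE 0.031) and KRT80, a keratin, fell by 1.01 (SE 0.036). NGRN fell by 1.28 and has a seed site. These genes passed with the library GC score as a covariate too.

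The rise of GC-rich genes was weighed first. Library size is argued against, since siELF5 replicate 1 and siNC replicate 2, with 83.7 M and 83.3 M reads, differed by 0.442 in GC score. GC bias of the libraries may account for it, since the siNC libraries alone spanned 0.293 in the median deviation of the GC-rich genes, 0.691 of the difference of 0.424 between the group means, or 0.127 and 0.365 of the difference without siNC replicate 1 and 0.166 and 0.336 without siNC replicate 3. The siELF5 libraries spanned only 0.052. An effect of the siRNA on GC-rich genes cannot be told apart from this, because the lowest siELF5 score lay 0.295 above the highest siNC score and the groups do not overlap.

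The second pattern is that genes with CACTAAC in the 3' UTR were lower in siELF5, with a log2 change of -0.133 per site and t = -11.4, where the lowest t in 100 permutations was -4.99. The model already held 3' UTR length and dinucleotide content, so base composition in that form was taken out of every t. Only what was left of it is argued against by the other orders of the same bases, since none without ACTAAC had t below -2.43. Off-target silencing by a seed in the ELF5 siRNA may account for it: in 1 model of both, the change per site was -0.132 (SE 0.011) in the 3' UTR and -0.034 (SE 0.014) in the coding sequence, and the coding value minus 0.5 times the other was 0.032 (95% interval 0.002 to 0.061), a narrow margin for a motif picked as the lowest in the 3' UTR, while its t of -8.31 in held-out genes was largely fixed by its value in all genes. A site in the ELF5 transcript, as the antisense strand would need, is argued against, with CACTAAC in 0 of 6 GENCODE 29 transcripts. Looked at after that result, the reverse complement GTTAGTG, which a sense strand would carry, is in 4 of 6, where 22.3% of all 7-base motifs are in at least 1, and the siRNA sequence is not given in the sources used here.

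The third pattern is the rise of estrogen response genes. GC bias as the whole cause is argued against, since the list's median log2 fold change was 0.289 after the GC correction (95% bootstrap interval 0.223 to 0.462) and 0.262 with the library GC score as a covariate (0.144 to 0.415). These intervals measure the spread between members, which share the same 6 libraries, and not the spread between libraries. With the GC score 11 of the 30 members passed upward and 2 downward. In the motif search 5 motifs of rising genes (CACATCA, CAATACA, ACATCAA, AGCCTTA and AATACAA, t of 5.43 to 6.85) lay above the highest permuted t of 5.17, beside 2 motifs of falling genes below the lowest. Release from a seed of the control siRNA cannot be told apart, because the 16 of 29 searched members with none of these 5 motifs are too few: their median was 0.229, with an interval of -0.035 to 0.454, against 0.344 (0.26 to 0.638) in the 13 with one, and 44.8% of the members carried one against 35.9% of other genes (Fisher's exact test, two-sided p = 0.336). Whether loss of ELF5 itself raised these genes was not tested, since each group received a single siRNA.

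The 6 libraries make 10 splits into 3 and 3, so no share of splits under 0.05 can be reached, and 1 split, the real one, gave counts as large. The real split gave 7559 genes changed (3818 higher, 3741 lower) by limma, and each other split gave 0, with 77 to 324 genes at an unadjusted p under 0.05. For gene lists the real split gave 8, the lowest other 1 and the highest other 5. Every other split has libraries of both groups on each side. The real difference then adds to the spread within sides, so the 0 genes was close to fixed in advance. Part of that difference also remains between the sides. Camera with the preset correlation called lists in these splits, and whether those are false calls or part of the real difference cannot be told apart.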
